A study of Mus musculus with 8 samples.

How the data were processed

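Gene expression and T cell receptor libraries of sorted live CD45-positive cells from liver metastases of 2 Vav1-Cre Tet2 knockout and 2 floxed control mice were analysed, 8 libraries in all, each targeting 10000 cells. Per the submitters' processing notes, reads were processed with Cell Ranger 8.0.1 against GRCm39, and Seurat 5.0.1 and R 4.4.1 were named as tools. As deposited, the matrices hold UMI counts per gene and cell barcode with no scaling, and the contig tables hold UMI counts and read counts per assembled receptor contig. The other deposited columns are barcodes and gene names, which hold no measurement. The files were tested for whole numbers, matching sizes and shared barcodes, and the features were identical in the 4 mice (33696 genes). The settings of the submitters' cell calling and the annotation release were not given.

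Barcodes with at least 200 genes and at most 10% mitochondrial UMIs were kept. Of 10917, 11743, 12494 and 13870 barcodes in knockout mice 1 and 2 and control mice 1 and 2, 10741, 11594, 12281 and 13598 passed. Doublets were called per library by Scrublet with its automatic threshold at an expected rate of 0.8% per 1000 cells, and 309, 471, 447 and 515 were removed. Median UMIs per barcode were higher in control libraries, but lower within every class tested for genes except monocyte/macrophage-like cells. Receptor UMI shares were therefore compared after thinning cells to 1000 UMIs, Tet2 UMI shares were not thinned, and genes were tested within classes.

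Counts were scaled to 10000 per cell and log transformed, and 2000 variable genes, 30 principal components, 20 neighbours and Leiden clustering at resolution 1 gave 33 clusters. Clusters were named from fixed marker genes (at least 3 markers with a fold of 2 and detection in 10% of cells), and clusters with no clear class or with doublets over 25% stayed unnamed. The marker names Tcrg-C1 and Tcrg-C2 were absent from the features. T-like clusters were clustered again (20 components, resolution 0.8, 15 sub-clusters). CD8 T cells were cells of T-like clusters with a UMI of Cd8a or Cd8b1 and no Cd4 UMI, and CD4 T cells the reverse, Treg-like cells being the CD4 T cells of the sub-cluster named so. CD4 clonality counted both.

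UMI counts were summed per mouse and class, for the planned classes with at least 30 cells in every mouse. Treg-like cells had too few, and plasmacytoid dendritic-like, plasma-like, proliferating, other T and unnamed cells were not among the classes planned for gene tests; these were compared as shares. Genotypes were compared by edgeR 4.0.16 quasi-likelihood tests (robust fit, filterByExpr, TMM factors, two-sided, Benjamini-Hochberg adjustment within a class, threshold 0.05). The 24 fixed gene lists were tested by camera of limma 3.58.1 with a correlation of 0.01, for lists with at least 5 tested members. Class shares were tested by edgeR on cell numbers and by exact two-sided permutation over mice. The genotype effect in CD8 T cells against that in monocyte/macrophage-like cells, expanded against single-cell clones, and the genotype by clone class term were edgeR tests with mouse as a block. Clones shared the V and J segments and CDR3 nucleotides of the productive beta chain with most UMIs, and clonality was the mean of 100 draws of equal cell numbers. TRBV segments with at least 10 clones were tested by edgeR on clone numbers. Those adjusted p values rest on the spread that edgeR pools over genes, with 2 mice per group.

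Genes were named by a fixed rule: per class, the 10 largest changes in each direction among called genes with both knockout mice on 1 side of both control mice and a mean of at least 20 CPM (4 in each direction outside CD8 T and monocyte/macrophage-like cells), called members of the lists (at most 4 per list, by p), and a fixed set of receptor, effector and myeloid genes, some of which are not reported here. Genes called prone to free RNA were those whose expected free RNA reached 20% of the higher group's level. It was estimated from the level of another lineage's genes in the class against the library, and from the library's total profile. That lineage was macrophages in T, NK-like and B-like cells and B cells in the other fitted classes. Folds against a group with no counts were taken against a floor of 3 counts over the group.

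Alternatives were 49 planned changes of normalization, filter, test (DESeq2 1.42.0), block, doublets, cell filters (500 genes and 5%), gate, resolution (0.5 and 2), thinning (2000), clone definition and leaving out each mouse. Added after the data were seen were fits without genes prone to free RNA, within single clusters, among cells that are not B-like, without the largest clones, and a clustering of T cells without called genes. The gene tests were tested on simulated data in which 200 genes were changed 2-fold or 4-fold: in CD8 T cells 35.7% and 92.0% were recovered, in NK-like cells 60.4% and 94.4%, in monocyte/macrophage-like cells 50.4% and 85.1%, in neutrophil-like cells 14.4% and 69.7%, in B-like cells 32.1% and 87.5%, in conventional dendritic-like cells 56.3% and 89.8%, and in CD4 conventional T cells 19.3% and 81.3%. Unchanged genes were 16.0% of the calls in CD8 T and 13.2% in NK-like cells, above the 5% set by the threshold, and 5.94% to 8.24% in the other classes. Further tools were Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and statmod 1.5.0.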

Results

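Leukocytes from liver metastases were profiled cell by cell to ask how loss of Tet2 in blood cells changes the immune infiltrate of a metastasis and the state and clonality of its T cells. Tet2 encodes a dioxygenase that oxidises methylated cytosine in DNA. The knockout mice carried Vav1-Cre, a recombinase active across the blood lineages, with floxed Tet2, and the control mice carried floxed Tet2. The tumours grew from Venus-AKTPM/LOH cells, a colorectal cancer line injected into the spleen, and were taken at day 30. Live CD45-positive cells were sorted from them, so the cells are leukocytes by selection. Each of 2 knockout and 2 control mice gave a gene expression library read from the 5' end of transcripts and a library of T cell receptor (TCR) transcripts. Total unique molecular identifiers (UMIs, counted molecules) were 57190926 in knockout mouse 1, 60456627 in knockout mouse 2, 89945864 in control mouse 1 and 91789597 in control mouse 2. Medians per barcode were 3739, 3726, 6639 and 6225.5 in that order. After filtering, 10432, 11123, 11834 and 13083 cells were used. The receptor libraries held 4536, 4852, 2631 and 3191 contigs. Groups, tests, gene lists and the rule for naming genes were chosen before the data were examined. Values after ± are SDs over the 2 mice of a group for levels and shares, and standard errors for log2 changes of knockout over control. Genes are said to have risen or fallen, or to be called, where the adjusted p from edgeR was under 0.05, and gene lists to be called where that from camera was. Unless described otherwise, intervals are 95% exact binomial (Clopper-Pearson) or counting intervals and cover counting error only. With 2 mice against 2 the smallest two-sided exact permutation p is 0.33.

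Tet2 (ENSMUSG00000040943) was measured first in every mouse as a check of the labels. Over all cells it was lower in both knockout mice, at 37.7 and 32.4 CPM (UMIs scaled to the total of the library), than in both control mice, at 66.1 and 65.6 CPM. Unthinned, a Tet2 UMI was seen in 15.3% (14.7 to 16.0) and 13.5% (12.9 to 14.1) of knockout cells and in 32.6% (31.8 to 33.5) and 31.4% (30.6 to 32.2) of control cells, but class mix and depth per cell differed between groups. Within B-like cells, deeper in knockout mice, the shares were 9.77% and 8.70% against 10.5% and 8.44% (31.7 and 28.4 against 49.0 and 34.0 CPM). Within CD8 T cells they were 11.8% (10.1 to 13.7) and 10% (8.30 to 11.9) against 14.8% (11.98 to 18.04) and 12.3% (9.81 to 15.1), and within monocyte/macrophage-like cells 31.6% (28.6 to 34.7) and 29.0% (26.5 to 31.7) against 43.7% (42.5 to 44.9) and 39.3% (38.2 to 40.4). CPM of gene tests are UMIs of the summed cells scaled to their total and divided by the TMM factors of that fit. In the fits of single classes, Tet2 fell in monocyte/macrophage-like cells, by 0.62 ± 0.11 on the log2 scale (46.5 ± 0.0441 against 71.3 ± 2.36 CPM, adjusted p = 0.0114), where scaling to the total alone gave 49.5 and 46.3 against 68.5 and 69.7 CPM. That adjusted p was 0.142 without knockout mouse 1 and 0.124 without knockout mouse 2. In the other fitted classes the log2 change was between -0.56 (NK-like, adjusted p = 0.116) and -0.16 (neutrophil-like, adjusted p = 0.82), none past the test. Gene-level UMIs do not show which part of the transcript they come from, and the labels do not name the floxed exon.

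The makeup of the infiltrate was compared first. B-like cells made up 43.1% ± 1.51 of the knockout cells and 5.24% ± 0.758 of the control cells, a ratio of 8.23. Monocyte/macrophage-like cells, the phagocytes that dominated the control tumours, made up 9.83% ± 1.30 against 58.2% ± 3.87, a ratio of 0.169. CD8 T cells, which kill infected and tumour cells, made up 11.3% ± 1.86 against 4.73% ± 0.00597. Conventional dendritic-like cells, which present antigen to T cells, made up 3.69% ± 0.187 against 1.46% ± 0.188, and CD4 conventional T cells 3.28% ± 0.667 against 1.54% ± 0.356. Neutrophil-like cells made up 3.67% ± 1.98 against 12.8% ± 2.67.

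Of 13 classes, 7 were called by edgeR on cell numbers. B-like cells rose (log2 change 3.04, adjusted p = 0.0029), as did conventional dendritic-like (1.34, 0.0240), CD8 T (1.26, 0.0248), unnamed (0.97, 0.0364) and CD4 conventional T cells (1.08, 0.0464), while monocyte/macrophage-like (-2.56, 0.0029) and neutrophil-like cells (-1.80, 0.0364) fell, with both knockout mice on 1 side of both control mice in each. NK-like cells (10.9% ± 0.823 against 4.70% ± 2.40), Treg-like cells (0.280% ± 0.112 against 0.688% ± 0.173) and plasmacytoid dendritic-like cells (1.77% ± 0.166 against 0.20% ± 0.247) had adjusted p of 0.0649, 0.0505 and 0.0760. Plasma-like cells were at 0.465% ± 0.0342 against 0.436% ± 0.173. The two-sided exact permutation p was 0.33 for every class whose mice separated. Without knockout mouse 1 or knockout mouse 2, 0 classes were called (the adjusted fit rests on a single knockout mouse), without control mouse 1 10 were, and with TMM factors over the classes 4 were and CD8 T cells were not (0.54, adjusted p = 0.22). The log2 change of CD8 T cells ran from 0.54 to 1.41 over its alternatives. Shares sum to a fixed total, so the rises can follow in part, for some classes wholly, from the fall of monocyte/macrophage-like cells. Shares among other cells were not tested, so growth in number is not shown.

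**Figure D1:**
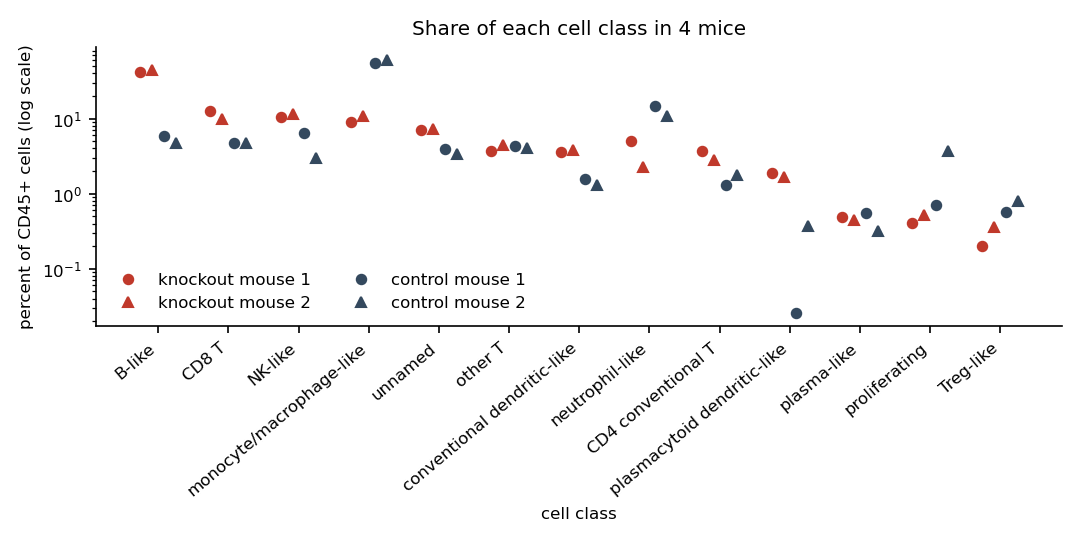
Percent of used cells (log axis) in each cell class for the 2 knockout and 2 control mice, each point a mouse. B-like cells sit at 42.1% and 44.2% in the knockout mice against 5.78% and 4.71% in the control mice, and monocyte/macrophage-like cells at 8.91% and 10.8% against 55.4% and 60.9%.

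RNA of cells that the sort should remove was counted over whole libraries, with all barcodes, and scaled to the library totals. Endothelial and stromal genes summed to 60.4 ± 4.74 CPM in the knockout and 25.5 ± 5.82 CPM in the control libraries, and erythroid genes to 61.8 ± 54.0 against 200 ± 45.9 CPM. Hepatocyte genes summed to 116 ± 11.3 against 630 ± 168 CPM, of which Trf and Apoc1, also expressed by macrophages, gave 98.6 ± 2.86 and 626 ± 169 CPM. The remaining 13 hepatocyte genes summed to 23.7 and 11.8 CPM in the knockout mice and 4.41 and 3.06 CPM in the control mice. Tumour epithelial genes summed to 23.9 ± 0.673 against 18.5 ± 6.26 CPM. The two-sided exact permutation p of the lists was 0.33 each.

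In CD8 T cells the comparison asked which genes differ between genotypes, with exhaustion, the dysfunctional state of chronically stimulated T cells, as the stated interest. Il7r, the receptor for the survival cytokine IL-7, rose by 1.69 ± 0.21 (599 ± 74.6 against 186 ± 48.3 CPM, adjusted p = 0.0132) and was called in 17 of 17 alternatives. Ifit3, an antiviral interferon-induced gene, rose most among genes not prone to free RNA, by 2.49 ± 0.26 (42.1 ± 2.54 against 7.52 ± 2.98 CPM, adjusted p = 0.00581). Klrc1, which encodes the inhibitory receptor NKG2A, rose by 1.64 ± 0.15 (394 ± 32.4 against 126 ± 6.57 CPM, adjusted p = 0.00324, with -0.14 within naive-like sub-clusters, not called), and Tgfbr1, a receptor chain for TGF-beta, by 1.48 ± 0.17 (49.2 ± 2.94 against 17.7 ± 0.246 CPM). Spp1, which encodes the secreted glycoprotein osteopontin, fell by 5.61 ± 0.49 (0.683 ± 0.769 against 31.9 ± 4.51 CPM, adjusted p = 0.00388), Cd81, a tetraspanin, by 4.37 ± 0.28 (3.62 ± 0.584 against 74.7 ± 22.9 CPM, adjusted p = 0.00143), and Irf8, an interferon-regulated transcription factor, by 2.13 ± 0.17 (18.3 ± 2.18 against 79.9 ± 0.768 CPM, adjusted p = 0.0025, with 0.032 within sub-cluster 7 and -1.11 within naive-like sub-clusters, not called). Also higher were Ifit1 (2.10), Ifit1bl1 (1.62), the chemokine receptor Ccr2 (1.45, 90.2 against 33.1 CPM), Irf7 (1.35), the activation-induced factors Nr4a3 (1.25) and Nr4a1 (1.03, with -0.052 within sub-cluster 7 and 0.40 within naive-like sub-clusters, not called), Hic1 (1.43), Lpar6 (1.63), Fam241a (1.68), Tex14 (1.48) and AW011738 (2.20). Also lower were Cib2 (-4.33), the decoy receptor Il1r2 (-2.97), the granzyme Gzmc (-2.78), Pkp4 (-2.27), Ece1 (-2.14), Tbc1d4 (-1.81), Cisd3 (-1.77), Smim36 (-1.72) and the signalling regulator Rgs16 (-1.41).

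Of 10726 genes tested in CD8 T cells, 82 rose and 98 fell, and 1821 had an unadjusted p under 0.05. The excess of falls was not kept within naive-like sub-clusters, where 59 rose and 31 fell. For naive-like sub-clusters 5 and 7 alone these counts were 40 and 17, and 33 and 12. Within the other sub-clusters 333 rose and 385 fell. Leaving out knockout mouse 1, knockout mouse 2, control mouse 1 or control mouse 2 gave 42, 76, 1458 or 247 called genes. Of the 40 called genes named here, 14, 22, 39 and 34 were called in those fits, and 11 in all 4. Of called genes tested within naive-like sub-clusters, 110 of 116 changed with the same sign there, at a median of 0.75 against 1.28 over all CD8 T cells. Those cells are also part of the class, so agreement in sign is in part built in. Of those named here, 6 of 28 tested within naive-like sub-clusters were called there with the same sign, 37 of 40 within the other sub-clusters, 5 of 23 within sub-cluster 5 and 2 of 15 within sub-cluster 7. The class was spread differently over T sub-clusters, also between the control mice: sub-clusters 0 and 1 held 34.8% and 23.1% of it in knockout mouse 1 and 35.0% and 22.5% in knockout mouse 2, sub-cluster 3 held 28.9% in control mouse 1 and 3.72% in control mouse 2, and sub-cluster 9 held 6.79% and 43.4%.

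The genes most used to read T cell exhaustion did not pass the main test. Pdcd1, which encodes PD-1, was at 201 ± 68.3 against 278 ± 113 CPM (-0.47 ± 0.37, adjusted p = 0.584), Havcr2, which encodes TIM-3, at 15.8 ± 3.94 against 31.6 ± 18.9 CPM (-1.0 ± 0.44, 0.339), Lag3 at 62.2 ± 19.8 against 103 ± 33.8 CPM (-0.73 ± 0.30, 0.294), and Tox, a driver of the exhausted state, at 80.5 ± 12.5 against 137 ± 7.88 CPM (-0.77 ± 0.16, 0.0605). Tigit (-0.30), Entpd1 (-0.22) and Ctla4 (0.10) lay closer to 0. The effector genes Ifng (1.18 ± 0.25, 502 ± 150 against 222 ± 51.6 CPM, adjusted p = 0.0781), Gzmb (0.14) and Prf1 (0.03), the cytotoxic genes Gzmk (-1.86) and Cx3cr1 (-1.30), the memory genes Tcf7 (0.39) and Slamf6 (-0.02), and Mki67 (-0.93) were not called either. Some passed in alternatives, with the same sign: Tox in 6 of 17, Ifng in 5 of 17, Havcr2 in 2 of 14, Lag3 in 2 of 15 and Pdcd1 in 0 of 14. Of 26 exhaustion genes, 2 rose (Nr4a3 and Nr4a1, which T cell receptor signals induce) and 1 fell (Rgs16), with 3 up and 3 down adjusted over the list alone. The list's median was -0.26 and its camera adjusted p was 0.294. That p was 0.0450 without control mouse 1 and 0.533, in the other direction, without control mouse 2, within a range of 0.0450 to 0.795 over its alternatives. Of 18 stem-like and memory genes, 1 rose (Il7r) and 0 fell, as when adjusted over the list alone. Their median was 0.08 and the camera adjusted p 0.437. Without control mouse 1 it was 9.17e-05 in the same direction, and without control mouse 2 it was 0.000912 in the opposite direction, the range being 9.17e-05 to 0.857. Of 22 cytotoxic effector genes, 1 rose (Klrc1) and 2 fell (Gzmc and Zeb2), with 8 up and 4 down adjusted over the list alone (median 0.13, camera adjusted p = 0.278).

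**Figure D2:**
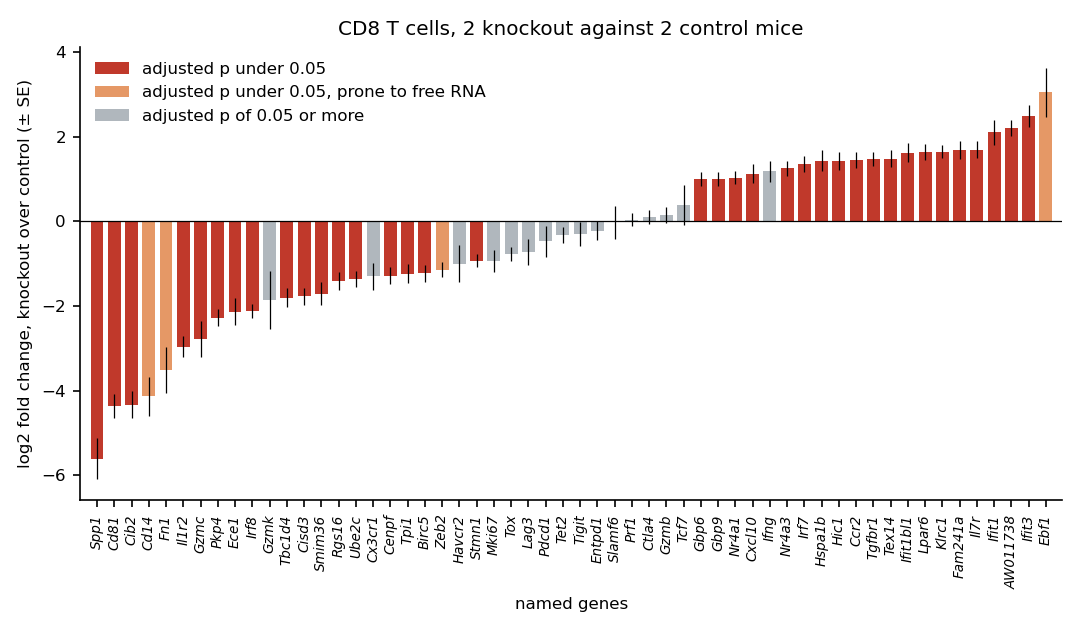
Log2 change of named genes in CD8 T cells, knockout over control, with standard errors as lines, called genes in red or orange (prone to free RNA) and others in grey. Il7r lies at 1.69 and Ifit3 at 2.49, while Pdcd1 (-0.47) and Lag3 (-0.73) were not called.

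Interferon genes and proliferation genes were tested as lists in CD8 T cells. Of 24 type I interferon genes, 6 rose (Ifit3, Irf7, Ifit1bl1 and Ifit1 first) and 0 fell, with 13 up and 0 down adjusted over the list alone. Their median was 1.31 and the camera adjusted p 2.41e-12. With an estimated correlation the adjusted p = 0.403 was the highest of its alternatives, and 2.00e-13 the lowest. Of 25 proliferation genes, 0 rose and 7 fell, with 0 up and 19 down adjusted over the list alone. They were led by Ube2c (-1.36 ± 0.19, 55.7 ± 11.1 against 143 ± 21.2 CPM), Cenpf (-1.29), the survivin gene Birc5 (-1.23) and Stmn1 (-0.93, 124 ± 14.0 against 236 ± 22.5 CPM). Their median was -0.90 and the camera adjusted p 2.41e-12 (adjusted p = 0.403 with an estimated correlation, range 2.00e-13 to 0.775). Within naive-like sub-clusters the list took the opposite direction (adjusted p = 0.0854). Of 23 interferon gamma genes, 3 rose (the guanylate-binding proteins Gbp9 and Gbp6 at 1.00 and 0.99, and the chemokine Cxcl10 at 1.12) and 0 fell, with 5 up and 0 down adjusted over the list alone. The median was 0.19 and the camera adjusted p 0.0143 (adjusted p = 0.553 with an estimated correlation, range 0.0014 to 0.795). It was 0.0761 without knockout mouse 2 and 0.124 without control mouse 1, and within naive-like sub-clusters it was 0.0340 in the opposite direction.

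Several other CD8 T lists passed camera with few called members. Of 21 dissociation stress genes, 1 rose (the heat shock gene Hspa1b, 1.43) and 0 fell, with 9 up and 0 down adjusted over the list alone. The median was 0.59 and the adjusted p 6.03e-05 (0.115 without control mouse 2, and adjusted p = 0.553 with an estimated correlation, range 5.85e-09 to 0.775). Of 18 Treg effector genes and 21 oxidative phosphorylation genes, 0 were called, with 1 up and 2 down and with 0 adjusted over the list alone. Their medians were -0.71 and -0.21 and their adjusted p 0.00504 and 0.00432 (adjusted p = 0.553 with an estimated correlation for both, ranges 2.51e-06 to 0.553 and 0.000627 to 0.775). The first was lost without control mouse 2 (0.0928) and the second without knockout mouse 1 (0.201). Of 9 immunosuppressive myeloid genes, 0 rose and 2 fell (Spp1, and Fn1, a matrix protein prone to free RNA), with 3 down adjusted over the list alone. Their adjusted p was 0.00324 (adjusted p = 0.403 with an estimated correlation, range 2.46e-05 to 0.403).

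Other lists of CD8 T cells were not called. Of 24 costimulation and receptor signalling genes, 1 rose (Nr4a1) and 0 fell, 2 and 1 adjusted over the list alone (median 0.16, mean -0.08, adjusted p = 0.28, range 0.0816 to 0.955). Of 18 hypoxia and glycolysis genes, 0 rose and 1 fell (Tpi1, -1.24), as adjusted over the list alone (0.278, or 0.0456 without knockout mouse 2, range 0.0456 to 0.919). Of 7 inflammatory cytokine genes, 0 rose and 1 fell (Il1r2), 2 and 3 adjusted over the list alone (0.229, range 0.000322 to 0.553). That list was called without knockout mouse 1 (0.000378), without knockout mouse 2 (0.00297) and without control mouse 2 (0.000912). MHC class I (15 genes, 0.331), MHC class II (11 genes, 0.272, or 0.000394 without knockout mouse 2, range 0.000394 to 0.811) and DNA methylation genes (11 genes, Tet2 among them, 0.204) had 0 called members, with 2 up, 2 down and 2 down adjusted over the list alone.

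RNA of other leukocytes was tested in the same comparison. In CD8 T cells 8 macrophage genes had a median of -1.51 (0 called, 6 down adjusted over the list alone, camera adjusted p = 1.17e-05), 5 neutrophil genes had an adjusted p of 0.000374, downward (Il1r2 called), and 6 neutrophil granule genes one of 0.000838. With an estimated correlation these were adjusted p = 0.553, 0.403 and 0.403, the ranges being 1.35e-08 to 0.553, 1.10e-06 to 0.403 and 5.28e-06 to 0.403. The granule list was at 0.0502 without control mouse 2. The 6 B cell genes had a median of 1.14 (Ebf1, prone to free RNA, called at 3.05, adjusted p = 0.00855, or adjusted p = 0.553 with an estimated correlation, range 0.000273 to 0.553), and were at 0.0525 without knockout mouse 2 and 0.174 without control mouse 2. Of the 180 called genes 13 (7.22%) were prone to free RNA, meaning that the expected free RNA, estimated from macrophage genes alone, reached 20% of the higher group's level. They included Cd14 (-4.14), Zeb2 (-1.14), Ebf1 and Fn1. Of the 10726 genes tested, 10540 were not prone.

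Receptor RNA was also read as the share of CD8 T cells with a UMI, after thinning each cell to 1000 UMIs (4, 3, 0 and 6 shallower cells were left out of knockout mice 1 and 2 and control mice 1 and 2). Pdcd1 was seen in 13.7% (11.9 to 15.7) and 17.7% (15.5 to 20.1) of knockout and in 13.4% (10.7 to 16.5) and 25.5% (22.1 to 29.1) of control CD8 T cells (two-sided exact permutation p = 1). Lag3 was seen in 4.2% (3.18 to 5.43) and 7.41% (5.93 to 9.11) against 5.54% (3.79 to 7.77) and 10.1% (7.86 to 12.8), and Tigit in 12.9% (11.1 to 14.8) and 14.3% (12.3 to 16.5) against 10.4% (7.96 to 13.2) and 21.1% (17.9 to 24.5). Ctla4 was seen in 15.4% (13.5 to 17.5) and 15.3% (13.2 to 17.5) against 11.3% (8.75 to 14.2) and 16.0% (13.2 to 19.2), and Tcf7 in 18.0% (16.0 to 20.2) and 15.7% (13.6 to 18.0) against 21.6% (18.3 to 25.3) and 8.33% (6.27 to 10.8). Havcr2 was seen in 1.22% (0.699 to 1.97) and 1.26% (0.693 to 2.11) against 1.96% (0.985 to 3.49) and 3.92% (2.53 to 5.78), and Tox in 7.86% (6.46 to 9.45) and 8.04% (6.51 to 9.80) against 11.4% (8.91 to 14.4) and 14.2% (11.5 to 17.2), each with a two-sided exact permutation p of 0.33. For Pdcd1, Lag3, Tigit, Ctla4, Tcf7 and Havcr2 the difference between the 2 control mice was larger than that between the groups. Without thinning, Pdcd1 was seen in 31.5% and 39.5% against 27.3% and 46.9%, and Tox in 27.5% and 29.8% against 34.3% and 39.3%. As a measure of background, thinned B-like cells held Pdcd1 UMIs in 0.0459%, 0, 0.148% and 0 of cells (0 in control mouse 2 allows up to 0.609%) and Ctla4 UMIs in 0.481% to 0.886%. Before thinning, median depths were 4698, 4532, 4445 and 4038 UMIs in the CD8 T cells kept for it and 3062, 2868.5, 2206 and 2410.5 in all B-like cells.

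**Figure D3:**
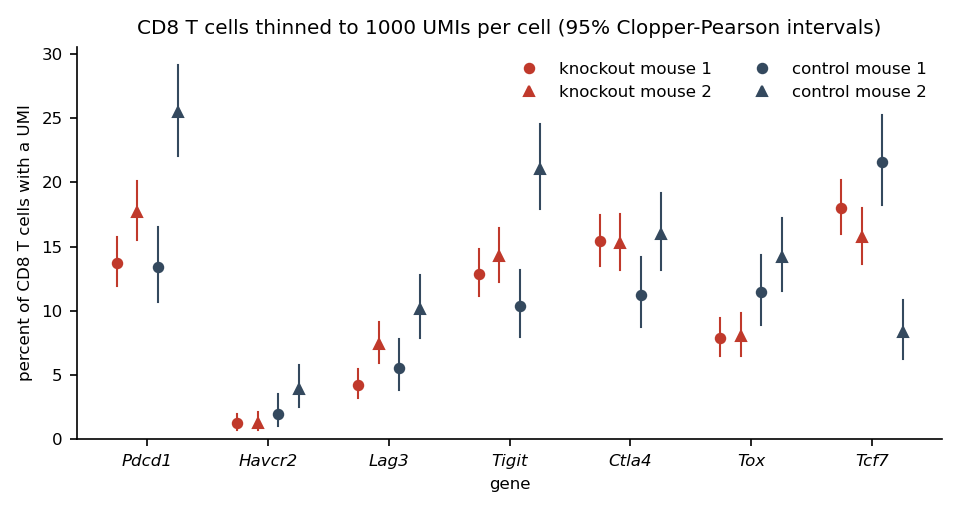
Percent of CD8 T cells with a UMI of each gene after thinning to 1000 UMIs, 1 point per mouse with 95% exact binomial intervals. Tox lies lower in both knockout mice (7.86% and 8.04%) than in both control mice (11.4% and 14.2%), while Pdcd1 is highest in control mouse 2 (25.5%).

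T cell states were compared after clustering without the 183 genes called in CD8 or CD4 T cells. An exhausted-like CD8 group made up 21.3% ± 2.08 of knockout and 2.63% ± 2.21 of control T cells (log2 change 3.01, adjusted p = 0.0993). Its markers were Pdcd1, Tigit, Ctla4, Nr4a2, Rgs16 and Cd160, without Havcr2, Lag3, Tox and Entpd1. A CD8 group with 3 effector memory markers made up 14.2% ± 0.186 against 3.28% ± 0.0907 (2.12, 0.0993), with 86.6% of its cells from sub-cluster 1, which the planned clustering left unnamed because its top genes held more markers of another class, and a Foxp3-led group, Foxp3 being the factor that defines regulatory T cells, 3.4% ± 1.85 against 15.3% ± 2.71 (-2.17, 0.0993). Another exhausted-like CD8 group, whose markers also included Havcr2, Lag3, Tox and Entpd1, made up 0.237% and 2.15% of knockout and 6.45% and 32.1% of control T cells (-4.01, 0.169). Of 15 groups, 0 were called by edgeR (4 at an unadjusted p under 0.05), against 4 with TMM factors, 7 without control mouse 1 and 0 without each other mouse. With all genes used for clustering, as planned, 3 of 15 were called. There sub-cluster 0 made up 21.3% ± 1.34 of knockout and 2.47% ± 2.55 of control T cells, and sub-cluster 1 14.2% ± 1.37 against 1.83% ± 0.702. The Treg-like sub-cluster made up 3.35% ± 1.85 against 15.4% ± 2.75, and sub-cluster 9 0.471% ± 0.129 against 14.5% ± 15.7.

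The T cell receptor libraries asked how clonal the T cells are, a clone being the cells of a mouse that share a receptor. At 521 CD8 T cells per mouse, expanded clones (2 or more cells) held 56.7% and 54.1% of cells in the knockout mice and 21.5% and 58.2% in the control mice (55.4% ± 1.81 against 39.8% ± 26.0, two-sided exact permutation p = 1). The 10 largest clones held 26.6% and 22% against 9.02% and 45.2%. The largest clone of control mouse 2, of 188 cells, held 32.1% (at the drawn number of cells) of its CD8 T cells, and 77.1% of it lay in sub-cluster 9. Without the largest clone of every mouse, expanded clones held 52.7% and 50.1% against 18.4% and 39.0% (two-sided exact permutation p = 0.33, the smallest possible). In sub-cluster 0 expanded clones held 381 of 399 and 319 of 343 knockout cells with a receptor (95.5% and 93.0%) and 30 of 49 and 5 of 8 control ones (61.2% and 62.5%), numbers that were not drawn to be equal, and more cells sampled make more clones count as expanded. At 189 CD4 T cells per mouse, expanded clones held 44.1% and 22.3% against 25.4% and 36.7% (two-sided exact permutation p = 1). Of 21 variable segments of the beta chain (TRBV), 0 were called by edgeR, and 1 (TRBV15) had an unadjusted p under 0.05 (0.0345). Invariant NKT receptors made up 2.71% (2.02 to 3.56) and 4.75% (3.84 to 5.80) of cells with an alpha chain in the knockout and 2.23% (1.44 to 3.31) and 1.46% (0.883 to 2.27) in the control mice (two-sided exact permutation p = 0.33). NK-like cells held 163 and 229 of the cells with an alpha chain in the knockout and 43 and 26 in the control mice, and among T-like cells the invariant share was 0.191% (0.0394 to 0.557) and 1.45% (0.910 to 2.18) against 1.54% (0.863 to 2.52) and 0.668% (0.289 to 1.31). MAIT receptors made up 0.325% (0.119 to 0.707) and 0.991% (0.598 to 1.54) against 0.186% (0.0226 to 0.671) and 0.385% (0.125 to 0.896), with a p of 0.667.

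**Figure D4:**
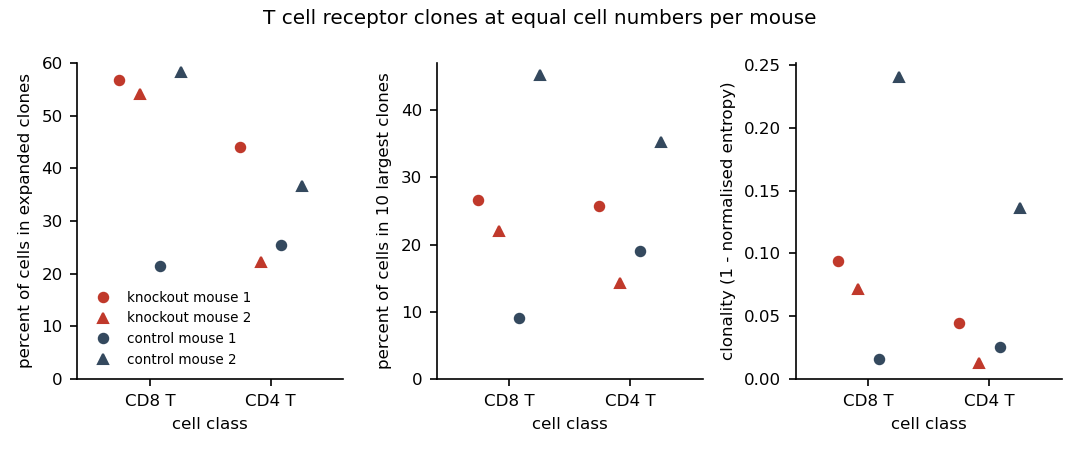
Percent of cells in expanded clones, percent in the 10 largest clones, and clonality (1 minus normalised entropy) of CD8 and CD4 T cells drawn to equal numbers, 1 point per mouse. In CD8 T cells control mouse 2 is highest in all 3 (58.2%, 45.2% and 0.240) and control mouse 1 lowest (21.5%, 9.02% and 0.0156).

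Expanded CD8 clones were compared with clones of a single cell within the same mice, to see which genes go with clonal growth. The 2 clone classes lay in different sub-clusters: in naive-like sub-cluster 3, 6 of 191, 0 of 152, 0 of 148 and 0 of 23 cells with a receptor in knockout mice 1 and 2 and control mice 1 and 2 were in expanded clones, against 381 of 399 and 319 of 343 in sub-cluster 0 of the knockout mice and 232 of 257 in sub-cluster 9 of control mouse 2. The comparison does not separate clonal growth from that mix of naive-like and other cells. Pdcd1 rose by 2.69 ± 0.19 in expanded clones (418 ± 116 against 71.2 ± 39.1 CPM over the 4 mice, adjusted p = 3.62e-05), with log2 differences of 3.04 and 3.17 in the knockout and 2.14 and 2.35 in the control mice. The chemokines Ccl3 (2.78 ± 0.14, 2.10e-07) and Ccl4 (2.46 ± 0.10, 9.77e-09), the granzyme Gzma (1.88), Havcr2 (2.31), the ectonucleotidase Entpd1 (1.94), the tissue-residence integrins Itga1 (2.67) and Itgae (0.99), Hic1 (2.60), Nr4a2 (1.62), Id2 (1.56) and Nkg7 (0.91) rose as well. Lef1, a transcription factor of naive and memory T cells, fell by 3.47 ± 0.12 (36.0 ± 10.2 against 391.5 ± 108.8 CPM, adjusted p = 1.78e-09), and Igfbp4 (-8.28), Dapl1 (-5.72), Il6ra (-4.48), Klf2 (-2.57), Slamf6 (-1.91) and Bcl2 (-1.05) fell too, in 4 of 4 mice each.

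Of 9387 genes, 924 rose and 933 fell in expanded clones. Of 25 exhaustion genes 20 rose and 1 fell (Eomes), with 22 and 1 adjusted over the list alone (median 1.56, camera adjusted p = 9.93e-13, or 0.305 with an estimated correlation). Of 18 stem-like and memory genes 1 rose (Xcl1, a chemokine of activated T cells) and 14 fell, with 1 and 15 adjusted over the list alone (median -2.46, 8.36e-11, or 0.305 with an estimated correlation). Of 21 cytotoxic effector genes 14 rose and 0 fell, with 16 and 0 adjusted over the list alone (median 1.24, 6.74e-10, or 0.305 with an estimated correlation). Of 18 Treg effector genes, which include Icos and Entpd1, 12 rose and 0 fell, the same numbers as when adjusted over the list alone (8.37e-07, or 0.305 with an estimated correlation). Leaving out knockout mouse 2 gave 1208 called genes in place of 1857.

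The difference between expanded and single-cell clones differed between genotypes in 413 genes, 258 with a higher and 155 with a lower difference in the knockout mice. Expanded cells lay in different sub-clusters: of 721 and 583 in the knockout mice, 381 and 319 lay in sub-cluster 0 and 257 and 206 in sub-cluster 1, against 30 and 5 and 10 and 6 of 112 and 343 in the control mice, of which 23 and 232 lay in sub-cluster 9 and 24 and 66 in sub-cluster 12. The proliferating sub-cluster 11 held 9 and 8 of the knockout and 18 and 24 of the control ones. In control mouse 2 a single clone gave 188 of the 343 expanded cells, and no fit of this test left out that clone alone. The test does not separate a change within states from this mix or from that clone. The genes named here were chosen after their values were seen, as those with the smallest p. Il7r differed most firmly, by 2.44 ± 0.17 (adjusted p = 4.18e-11): expanded over single-cell clones it was at 0.22 and 0.19 in the knockout and -2.59 and -2.03 in the control mice. Klrk1, which encodes the activating receptor NKG2D (2.53, 5.36e-06), Klrc1 (1.48, 4.67e-07), Fos (1.43), Socs1 (1.51) and the heat shock gene Hspa1b (1.72) were also higher in knockout expanded clones relative to single-cell ones. The cell cycle genes Top2a (-2.05 ± 0.19, 5.04e-08), Birc5 (-2.23), Ube2c (-2.02), Cdk1 (-2.55) and Stmn1 (-1.63) went the other way, Top2a being at -0.60 and -0.40 in the knockout and 1.59 and 1.44 in the control mice. The count was 220 without knockout mouse 1, 621 without control mouse 1, 121 without cells with an Mki67 or Top2a UMI, and 59 with DESeq2.

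NK-like cells, innate killers, were compared next. Isg15, an interferon-induced ubiquitin-like protein, rose by 2.29 ± 0.23 (271 ± 3.54 against 53.2 ± 22 CPM, adjusted p = 0.00176), the cytokine gene Tnf by 1.54 ± 0.15 (114 ± 5.68 against 39.0 ± 1.92 CPM, 0.00031), and Lag3 by 1.70 ± 0.23 (71.9 ± 5.84 against 23.7 ± 10.1 CPM, 0.00296). Gzmk fell by 2.85 ± 0.28 (5.56 ± 1.70 against 41.2 ± 11.5 CPM, 0.00034), and the maturation marker Klrg1 by 1.57 ± 0.15 (40.7 ± 2.25 against 119 ± 18.1 CPM, 0.00031, with -0.33 within cluster 11 and 0.074 within cluster 6, not called in either). The T cell receptor complex genes Cd3g (1.99, 800 ± 112 against 204 ± 71.8 CPM) and Cd3e (1.57), the liver-residence chemokine receptor Cxcr6 (1.73), the protease Mmp9 (3.21), Cd200r2 (2.73), Icos (1.06), Nr4a3 (0.99) and Klrc1 (0.89) rose, and the inhibitory receptor Klra3 (-1.98), Dhrs3 (-1.98), Wdr95 (-1.74) and Lef1 (-0.97) fell. Ifng (0.81), Gzmb (0.48) and Prf1 (-0.99) were not called. A beta chain was seen in 19.7% (17.4 to 22.2) and 22.6% (20.4 to 25.0) of knockout and in 7.27% (5.52 to 9.35) and 8.91% (6.28 to 12.2) of control NK-like cells. The class therefore held T cells in both genotypes, and a larger part of them in the knockout mice. No fit left those cells out. The changes of this class, Cd3g, Cd3e and Icos among them, are thus not separated from that larger part of T cells.

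Of 10633 genes, 359 rose and 288 fell in NK-like cells, and 11 of 20 lists were called (0 with an estimated correlation). Of 22 type I interferon genes 11 rose and 0 fell (17 and 0 adjusted over the list alone, median 1.21, camera adjusted p = 1.09e-09). Of 23 interferon gamma genes 8 rose (Gbp6 at 1.94 and Gbp9 at 1.10 among them) and 1 fell, with 11 and 2 adjusted over the list alone (0.000681, or 0.0554 without control mouse 1). The adjusted p = 0.503 with an estimated correlation for both lists, over ranges of 2.48e-12 to 0.503 and 0.000647 to 0.692. Of 23 costimulation and receptor signalling genes 8 rose (Icos, Cd3e and Cd3g among them) and 1 fell, with 8 and 2 adjusted over the list alone (0.0278, range 0.0227 to 0.566, adjusted p = 0.566 with an estimated correlation, with 0.0963 without knockout mouse 2, 0.0554 without control mouse 1 and 0.119 without control mouse 2). Of 24 exhaustion genes 4 rose (Nr4a3, Lag3, Cxcr6 and Cd200r1) and 1 fell (Rgs16), with 9 and 3 adjusted over the list alone (median 0.25, 0.0483, range 0.0211 to 0.760, adjusted p = 0.523 with an estimated correlation, 0.0963 without knockout mouse 2 and 0.117 without control mouse 1). Within cluster 6 that list took the opposite direction (0.760), with Cd200r1 at -0.18, not called. Macrophage genes were lower there (7 genes, 1 down, 6 adjusted over the list alone, 0.00042, or adjusted p = 0.503 with an estimated correlation, range 8.73e-06 to 0.503). Cluster 6 held 71.5% and 73.5% of the class in knockout mice, and cluster 11 held 84.4% and 61.6% in control mice. Within cluster 6 alone 212 genes were called and within cluster 11 alone 99, and 558 of 586 and 491 of 530 of the calls tested there had the sign they have over the class, whose sums include these cells. Of the called genes named here, 2 of 20 and 5 of 17 tested were called there with that sign. The counts were 227, 250, 1255 and 1421 without knockout mouse 1, knockout mouse 2, control mouse 1 and control mouse 2 in order.

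Monocyte/macrophage-like cells were compared for inflammatory, suppressive and metabolic genes. Arg1, the arginase of suppressive macrophages, fell by 4.97 ± 0.41 (15 ± 0.274 against 473 ± 215 CPM, adjusted p = 0.00503, with 0.073 without knockout mouse 1 and 0.066 without knockout mouse 2). Hilpda, a hypoxia-induced lipid droplet protein, fell by 2.49 ± 0.16 (53.4 ± 10.2 against 300 ± 2.01 CPM, 0.000485), and the oxygen sensor Egln3 by 2.81 ± 0.23 (6.68 ± 2.10 against 47.1 ± 7.80 CPM, 0.00164). Neither was called within every cluster: Hilpda was at -0.46 in cluster 3 and -1.33 in cluster 14 and Egln3 at -0.61 in cluster 3 and -1.13 in cluster 9, not called. Hpgd, which breaks down prostaglandins, rose by 2.48 ± 0.17 (262 ± 52.0 against 46.9 ± 4.92 CPM, 0.000822), and Ace, a marker of patrolling monocytes, by 1.97 ± 0.18 (102 ± 24.5 against 26.0 ± 3.02 CPM, 0.00211). Ace was not called within single clusters, at -0.025 and -0.32 in clusters 1 and 9 and 1.08 and 0.82 in clusters 3 and 14. Of the called genes named for this class, 25 of 37 tested within cluster 1, 18 of 33 within cluster 3, 17 of 36 within cluster 9 and 18 of 35 within cluster 14 were called there with the same sign. S1pr5 (4.37), Adgre4 (2.35), Pglyrp1 (2.46), Pparg (2.16), Gpnmb (2.5), Heg1 (2.06), Stap1 (1.89) and Hspa1a (1.86) rose, and Htra3 (-5.91), Eps8 (-3.29), Ppp1r3b (-3.03), Jaml (-2.58), Slc7a2 (-2.49) and the antigen-processing thiol reductase Ifi30 (-1.87) fell. The T cell attracting chemokine Cxcl9 rose by 1.00 ± 0.18 (310 ± 78.1 against 155 ± 1.62 CPM, 0.0138). Il1b (-0.41, adjusted p = 0.0749), Spp1 (-2.03, 0.132), Tnf (0.69) and H2-Ab1 (0.37) were not called.

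Of 13962 genes, 912 rose and 1079 fell in monocyte/macrophage-like cells, and 16 of 23 lists were called (0 with an estimated correlation). Of 18 hypoxia and glycolysis genes 0 rose and 17 fell (Ero1a at -2.02, Bnip3 at -1.91, Tpi1 at -1.41 and Egln3 first), 18 adjusted over the list alone, with a median of -1.17 and a camera adjusted p of 1.02e-10. Of 22 inflammatory cytokine genes 0 rose and 6 fell (Il1a at -1.65, Osm at -1.76 and Il6 at -1.55 among them), 10 adjusted over the list alone (median -0.98, 0.00318, or 0.109 without control mouse 1, and 0.850 in the opposite direction within cluster 1). Of 26 type I interferon genes 4 rose (Isg20 at 1.77, Mx2 at 1.67, Stat2 at 0.77, and Ifit1bl1) and 0 fell, 5 adjusted over the list alone (median 1.47, 2.65e-07). Of 15 MHC class I genes 6 rose (H2-T23 at 0.97 first) and 0 fell, 7 up and 1 down adjusted over the list alone (0.0322, or 0.214 without knockout mouse 2 and 0.067 without control mouse 1, and 0.485 in the opposite direction within cluster 9). Of 21 oxidative phosphorylation genes 0 rose and 8 fell, 1 up and 18 down adjusted over the list alone (median -0.39, 1.83e-05). Of 20 immunosuppressive genes 4 rose (Gpnmb, Folr2, Cd163 and Retnla, markers of alternatively activated or resident macrophages) and 6 fell (Fn1 at -1.29, Arg1, Mrc1 at -0.98 and Il4ra at -1.10 first), 4 and 8 adjusted over the list alone. That list's median was -0.55 and its adjusted p 0.0397, and it lost its call without knockout mouse 1 (0.0769), knockout mouse 2 (0.562) or control mouse 1 (0.111). With an estimated correlation the adjusted p = 0.516 for the hypoxia, oxidative phosphorylation and immunosuppressive lists, 0.608 for the cytokine and type I interferon lists and 0.613 for the MHC class I list. Over their alternatives the 6 lists, in the order given, ranged from 7.92e-11 to 0.516, 4.45e-06 to 0.850, 4.79e-12 to 0.703, 4.61e-07 to 0.613, 1.75e-05 to 0.556 and 0.00538 to 0.562.

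Genes of other cells were tested in these phagocytes as well. Of 9 B cell genes 6 rose (Cd79b at 1.77 and Ighm at 1.07, both prone to free RNA) and 0 fell, 8 adjusted over the list alone (median 1.79, 3.82e-05, or adjusted p = 0.516 with an estimated correlation, range 2.80e-06 to 0.516). Of 5 erythroid genes 5 fell, 5 adjusted over the list alone (2.65e-07, or adjusted p = 0.443 with an estimated correlation, range 7.88e-08 to 0.443). Hba-a2 had no knockout UMI. Only 17 to 137 barcodes per library held erythroid UMIs, so these falls rest on few cells. Of 6 endothelial and stromal genes 2 rose (Clec4g and Kdr, at 4.26 and 3.24), 3 adjusted over the list alone (0.0065, or adjusted p = 0.516 with an estimated correlation, range 0.00154 to 0.516). Of 19 cytotoxic effector genes 7 rose, S1pr5 first, 8 adjusted over the list alone (2.47e-05, or adjusted p = 0.443 with an estimated correlation, range 8.65e-06 to 0.443). Clusters 9 and 14 held 51.6% and 25.1% of the class in knockout mouse 1 and 49.6% and 23.7% in knockout mouse 2. Clusters 1 and 2 held 54.5% and 24.4% in control mouse 1 and 35.3% and 35.8% in control mouse 2. Within clusters 1, 3, 9 and 14 alone 740, 350, 467 and 456 genes were called, and 1754 of 1843, 1533 of 1612, 1593 of 1667 and 1484 of 1607 of the calls tested there had the sign they have over the class, whose sums include these cells. Besides Ace, the exceptions among called genes named here were Fn1 (0.36), Ifit1bl1 (-0.22) and Mx2 (-0.080) within cluster 9 and Bnip3 (0.088) within cluster 14, none of them called there. Without knockout mouse 1 59 genes were called, without knockout mouse 2 259, without control mouse 1 2672 and without control mouse 2 1995. Of the 40 called genes named here, 15, 29, 38 and 37 were called in those fits.

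**Figure D5:**
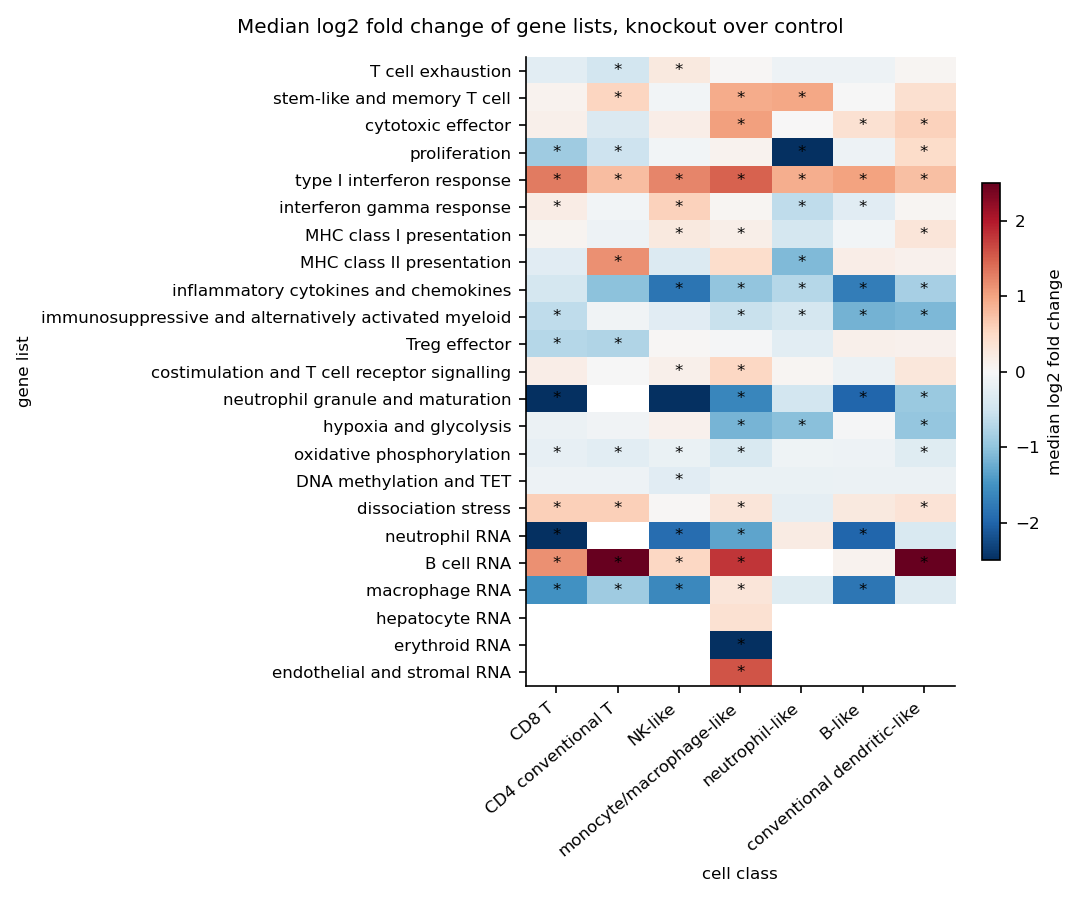
Median log2 change, knockout over control, of each gene list in each cell class, with the lists called by camera marked. The type I interferon list is at 1.31 in CD8 T cells and 1.47 in monocyte/macrophage-like cells, and the hypoxia list at -1.17 in monocyte/macrophage-like cells.

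Neutrophil-like cells were tested in the same way. Il23a, a subunit of the cytokine IL-23, fell by 4.61 ± 0.48 (3.27 ± 2.32 against 94.4 ± 27.7 CPM, adjusted p = 0.000804), Egln3 by 3.59 ± 0.40 (18.4 ± 6.20 against 211 ± 70.5 CPM, 0.00116), and Ero1a by 2.37 ± 0.32. Il1a (-3.45), Tpi1 (-1.84), Cd69 (-1.84), the prostaglandin synthase Ptgs2 (-1.27) and Tnfrsf18 (-2.68) fell. Elane, the elastase of immature neutrophils, had no UMI in the knockout mice and was at least 70.3-fold lower against the floor of 3 counts over the group, and Mki67 was lower by a ratio of 29.3 (8.0 to 244). Prok2 rose by 4.38 ± 0.62 (213 ± 70.5 against 10.3 ± 9.0 CPM, 0.0128), the clock repressor Ciart by 3.82 ± 0.32 (217 ± 44.0 against 15.4 ± 1.42 CPM, 0.000237), and Ifi27l2a (2.54), Batf (1.78) and Oas3 (1.30) rose. Cxcr2 (0.32), S100a8 (-0.06) and Il1b (-1.14, adjusted p = 0.0798) were not called. Of 8319 genes 265 rose and 197 fell. Of 18 hypoxia and glycolysis genes 0 rose and 5 fell, 11 adjusted over the list alone (median -1.05, 6.61e-06), of 19 proliferation genes 0 rose and 3 fell, 13 adjusted over the list alone (9.33e-06), and of 22 type I interferon genes 2 rose and 0 fell, as adjusted over the list alone (median 0.92, 0.00128, or 0.128 without control mouse 2). Each had adjusted p = 0.728 with an estimated correlation, over ranges of 3.08e-08 to 0.728, 4.42e-11 to 0.765 and 2.17e-08 to 0.728. Cluster 10 held 93.4% and 78.3% of the class in knockout mice, and cluster 8 held 62.2% and 54.0% in control mice. Cluster 24, led by granule genes of immature neutrophils, held 5.48% and 5.93% in knockout mice, 2.53% in control mouse 1 and 23.3% in control mouse 2. Within cluster 10 alone 443 genes were called, 187 up and 256 down, and the proliferation list was not (adjusted p = 0.765). Without a filter on low counts 403 genes rose and 554 fell, so the excess of rises was kept in neither fit. Leaving out knockout mouse 1, knockout mouse 2, control mouse 1 and control mouse 2 in order gave 225, 816, 1198 and 866 called genes, and 12, 14, 15 and 15 of the 15 called genes named here.

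In conventional dendritic-like cells Hpgd rose by 3.19 ± 0.21 (139 ± 22.1 against 15 ± 3.15 CPM, adjusted p = 4.07e-05) and Hes1, a Notch target, by 2.49 ± 0.29 (41.9 ± 0.735 against 7.15 ± 3.80 CPM, 0.00078), while Cdh1, which encodes E-cadherin, fell by 4.59 ± 0.46 (1.15 ± 0.0830 against 28.1 ± 14.5 CPM, 0.000627) and the mannose receptor Mrc1 by 2.27 ± 0.24 (12.7 ± 2.21 against 61.6 ± 17.6 CPM, 0.000627). Ifit3 (3.06), Hspa1a (1.54), the class II chaperones H2-Ob (1.46) and H2-Oa (0.99), Havcr2 (0.97) and H2-T22 (0.93) rose, and Cst7 (-1.73), Ifi30 (-1.43) and Cd200r1 (-1.41) fell. Of 10198 genes 503 rose and 561 fell, and 11 lists were called (0 with an estimated correlation). Of 18 hypoxia and glycolysis genes 0 rose and 13 fell, 13 adjusted over the list alone (median -0.97, 4.68e-09), of 25 type I interferon genes 4 rose and 0 fell, 9 adjusted over the list alone (median 0.74, 7.56e-05), and of 25 proliferation genes 3 rose (Hmgb2, Cenpe and Ube2c) and 0 fell, 3 adjusted over the list alone (median 0.46, 0.00015). Of 13 immunosuppressive genes 1 rose and 8 fell, 1 and 10 adjusted over the list alone (median -1.13, 5.47e-05), and of 15 MHC class I genes 6 rose and 0 fell, 7 adjusted over the list alone (0.00615, or 0.0675 without control mouse 1). All 5 had adjusted p = 0.459 with an estimated correlation, over ranges of 1.09e-11 to 0.459, 1.96e-07 to 0.459, 1.81e-05 to 0.473, 3.48e-06 to 0.459 and 0.00367 to 0.532. Of 9 B cell genes 5 rose, 9 adjusted over the list alone (median 2.69, 1.16e-05, or adjusted p = 0.459 with an estimated correlation, range 1.32e-08 to 0.459). Expected free RNA, estimated from B cell genes alone, was 9.35%, 13.7%, 15% and 33.5% of this class's UMIs in knockout mice 1 and 2 and control mice 1 and 2. Neutrophil genes gave 4.83%, 11.3%, 9.14% and 5.07% in the same order. Once genes prone by the first estimate were left out, 415 genes rose and 198 fell, so the excess of falls was not kept. Cluster 27, led by genes of cross-presenting dendritic cells, held 44.5% and 25.2% of the class in knockout and 21.3% and 18.5% in control mice, and cluster 15 the rest. Within clusters 15 and 27 alone 1376 and 447 genes were called, and 973 of 975 and 817 of 843 of the calls tested there had the sign they have over the class. As these 2 clusters make up the class, agreement in sign is in part built in. Hpgd was at 3.69 in cluster 15 and 1.44, not called, in cluster 27, and the proliferation list lost its call in cluster 27 (adjusted p = 0.473). The number called became 1514 without knockout mouse 2, 291 without control mouse 1 and 232 without control mouse 2, where 16, 11 and 8 of the 16 called genes named here were called.

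CD4 conventional T cells and B-like cells had few called genes. In CD4 conventional T cells, of 8788 genes 2 rose and 2 fell (821 at an unadjusted p under 0.05, 18 called by DESeq2): Klrk1 rose by 3.66 ± 0.44 (35.3 ± 2.97 against 2.77 ± 0.349 CPM, adjusted p = 0.0396) and Ccr9, a gut homing receptor, fell by 4.03 ± 0.43 (2.46 ± 1.00 against 41.3 ± 9.37 CPM, 0.0225), while Cd79a, a B cell gene prone to free RNA, was higher by a ratio of 45.8 (12.5 to 381). Of 19 Treg effector genes and 25 proliferation genes 0 were called, and 0 adjusted over the list alone (medians -0.75 and -0.51, camera adjusted p = 0.000185 and 3.13e-06, the latter 0.107 without knockout mouse 1). With an estimated correlation the adjusted p = 0.615 for both, over ranges of 3.81e-07 to 0.615 and 2.31e-11 to 0.617. Of 6 B cell genes 1 rose, 4 adjusted over the list alone (3.43e-07, or adjusted p = 0.446 with an estimated correlation, range 2.83e-11 to 0.446). Leave-one-out counts were 18, 62, 58 and 1 without knockout mouse 1, knockout mouse 2, control mouse 1 and control mouse 2 in order. Of the 3 called genes named here, 0 were called without control mouse 2 (Klrk1 0.362, Ccr9 0.357 and Cd79a 0.336), and with only cells with a TRB the adjusted p was 0.0535 for Klrk1 and Ccr9.

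In B-like cells, of 11452 genes 3 rose and 9 fell (1221 at an unadjusted p under 0.05, 67 called by DESeq2, and 3 up and 17 down with size factors). Without genes prone to free RNA 0 rose and 1 fell, and 1 of the 7 calls still tested was kept. Tgfbr1 rose by 1.68 ± 0.21 (61.5 ± 7.86 against 19.2 ± 2.80 CPM, adjusted p = 0.0472) and the tubulin gene Tubb4b by 1.64 ± 0.18 (241 ± 18.4 against 77.5 ± 4.87 CPM, 0.0322), and Rab30 fell by 1.79 ± 0.18 (26.6 ± 0.323 against 92.2 ± 16.5 CPM, 0.0322). Of 24 type I interferon genes 0 were called, 1 adjusted over the list alone (median 1.00, camera adjusted p = 2.20e-05, and adjusted p = 0.448 with an estimated correlation, range 5.76e-09 to 0.999). That list was not called without knockout mouse 2. Without genes prone to free RNA it took the opposite direction (camera adjusted p = 0.999). Of 10 macrophage genes 0 rose and 1 fell, 8 adjusted over the list alone (median -1.81, 1.22e-07, or adjusted p = 0.448 with an estimated correlation, range 3.93e-15 to 0.448). Cluster 0 held 68.1%, 71.2% and 70.2% of the class in knockout mice 1 and 2 and control mouse 1, and cluster 7 held 64.8% in control mouse 2. With knockout mouse 1, knockout mouse 2, control mouse 1 and control mouse 2 left out in order, 77, 56, 1175 and 71 genes were called.

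Whether the genotype effect differed between CD8 T and monocyte/macrophage-like cells was tested directly, in a fit of both classes whose TMM factors, and so CPM, differ from those of the single classes. Il7r differed by 2.69 ± 0.22 (adjusted p = 0.000261), being at 542 against 170 CPM in CD8 T cells and 4.10 against 8.56 CPM in monocyte/macrophage-like cells. The hypoxia genes Egln3 (3.24 ± 0.30, 0.000644), Ero1a (2.06), Slc2a1 (1.58) and Hif1a (1.22) and Hilpda (2.23 ± 0.17, 0.000207) also had a higher change in CD8 T cells: Hilpda was at 83.4 against 97.8 CPM there and at 58.8 against 326 CPM in monocyte/macrophage-like cells. Jaml (3.09), Ccr2 (1.91) and Nr4a3 (1.15) followed, while Cib2 (-4.10 ± 0.30, 0.000207), Ccr7 (-1.83), Stmn1 (-1.48), Id3 (-1.43) and Top2a (-1.19) had the lower change in CD8 T cells. Of 13005 genes 152 had a higher and 241 a lower change in CD8 T cells. Those counts summed to 393, against 153 without knockout mouse 1 and 1225 without control mouse 1.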

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

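The share among cells that are not B-like, the sum of 13 hepatocyte genes, the Pdcd1 background in B-like cells, the limit on free RNA in CD8 T cell calls and the choice of splits that part every pair were tests chosen only after the result was seen. Groups of 2 mice are too small for a test of single outlying samples. Tests of the difference itself picked out 393 genes whose genotype effect differed between CD8 T and monocyte/macrophage-like cells, and 413 whose effect differed between expanded and single-cell CD8 clones. Signals outside the main comparisons were picked out as well. A beta chain was seen in 21.2% of NK-like cells (mean of the knockout mice, against 8.09% in the control mice) and in 16.9% of cells of unnamed clusters (against 6.41%). Endothelial and stromal RNA was at 60.4 CPM in the knockout libraries, 2.37 times the 25.5 CPM of the control libraries, most of it Pecam1 (45.5 and 47.2 against 20.5 and 14.0 CPM), which leukocytes also express.

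B-like cells made up far more, and monocyte/macrophage-like cells far less, of the knockout samples. Shares sum to a fixed total, but among cells that are not B-like the monocyte/macrophage-like share was still lower in both knockout mice, at a ratio of 0.282, which argues against that arithmetic as the whole cause. A larger part of uninvolved liver in the knockout samples is a candidate explanation: the whole hepatocyte list pointed the other way (ratio 0.185), but 99.4% of its control UMIs lay in Trf and Apoc1, which macrophages express, so its planned reading was void. The 13 remaining genes were higher in both knockout libraries (ratio 4.76), at low levels (Alb at 7.75 and 4.66 against 0.589 and 0.697 CPM, Ttr at 4.77 and 2.08 against 0.289 and 0.185 CPM), although the CD45 sort should remove hepatocytes. The genotype itself stays open beside it as the untested biological explanation.

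UMIs of Pdcd1, Havcr2, Lag3 and Tigit were most frequent in the CD8 T cells of control mouse 2 in all 5 settings tried, while Ctla4 was more frequent in knockout mouse 2 when thinned to 2000 UMIs (25.7% against 24.2%) and in cells with a beta chain (17.1% against 16.4%), and in both knockout mice without the largest clones (16.1% and 15.5% against 13.6%). RNA from other cells is argued against for Pdcd1, since at most 0.609% of its B-like cells held it, against 25.5% of its CD8 T cells. Its largest clone may account for part of the gap: without the largest clone of every mouse its share was 20.2% (16.5 to 24.3), still above the 18.4% of knockout mouse 2 but with an interval that holds that value. The clone and a state shared by its other CD8 T cells cannot be told apart from these counts, and control mouse 2 is a single animal. No biological explanation was tested for a difference within the control group.

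Of the genes called between genotypes in CD8 T cells, 7.22% were prone to free RNA, as estimated from macrophage genes alone. By that estimate, expected free RNA in the other 167 is under 20% of the higher level. It then accounts for less than 0.322 of a log2 change, while the smallest of their changes was 0.736. B cell genes gave a higher estimate in every mouse, at 4.05% and 5.53% in the knockout and 16.46% and 15.01% in the control mice. Neutrophil genes gave 0.874% and 1.08% against 3.13% and 1.96%. The limit was not computed from either, so it cannot decide whether RNA from other cells caused most calls. A different mix of CD8 T cell states may account for part of the calls: within naive-like cells the median change was 58.9% (interval 47.1 to 69.2) of that over all CD8 T cells. A change within states and a change of their mix cannot be told apart here, because that interval reaches on both sides of the 50% set beforehand and the states were defined in part from these genes. Depth per cell differed little between the groups in this class (medians of 4693 and 4529.5 against 4445.5 and 4027 UMIs). The genotype stays open as the biological explanation.

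For the genes that differ between expanded and single-cell clones, every mouse gives a pair of sums, and 8 splits of the sums part all 4 pairs, too few for a share under 0.05. Of these 8, 1, the real one, gave 1857 genes, and the highest of the others gave 0. Another 24 splits part 2 pairs and leave 2 together, the highest of them giving 0, and 3 of 35 could not be fitted.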

How the results depend on the processing

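Fits without genes prone to free RNA, within single clusters or sub-clusters, among cells that are not B-like, without the largest clones and after clustering without called genes were chosen after the data were seen, the others before. Over 213 named gene results and 2652 alternatives, 2249 kept direction and side of the threshold, 323 kept direction only and lost the call, 40 gained it and 40 reversed. For 84 gene list results and 1036 alternatives these numbers were 698, 309, 9 and 20. For 39 other results and 388 alternatives, 263 stayed close, 7 lost their call and 118 moved. The cause was not tested for changes given below, except where fewer cells, genes or mice follow from the alternative itself.

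Without a filter on low counts 1056 genes were called in CD8 T, 317 in CD4 conventional T, 1255 in NK-like, 957 in neutrophil-like, 34 in B-like and 1728 in conventional dendritic-like cells, and 1096 in the test between CD8 T and monocyte/macrophage-like cells. DESeq2 called 18 in CD4 conventional T, 323 in NK-like, 67 in B-like and 535 in conventional dendritic-like cells, 1148 between expanded and single-cell clones and 59 for genotype by clone class. DESeq2 size factors in edgeR gave 20 in B-like cells. Gating by T sub-cluster side gave 113 in CD8 T and 140 in CD4 conventional T cells, with Prf1 at -0.13 and Slamf6 at 0.067, and CD4 cells with a beta chain gave 1. Keeping doublets put Slamf6 at 0.0083 and left 4 lists called in neutrophil-like cells. For genotype by clone class, clones of 5 or more cells gave 182 genes, and leaving out cells with Mki67 or Top2a gave 121. Without the mouse block 1002 genes were called between expanded and single-cell clones.

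The replicate block, under which mice share only a number, gave 37 genes in CD4 conventional T, 1135 in NK-like, 257 in neutrophil-like and 134 in B-like cells, 0 T sub-clusters, 1 after clustering without called genes, and put Slamf6 at 0.061 in CD8 T and S100a8 at 0.18 in neutrophil-like cells. Deviations of mice with the same number correlated at -0.05 to 0.12 over the classes.

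With an estimated correlation camera called 0 lists in each of the 7 classes, and fry called 1 in CD8 T, 1 in NK-like and 1 in monocyte/macrophage-like cells and 0 in the other 4. Without genes prone to free RNA 6 lists were called in CD8 T, 6 in NK-like, 7 in monocyte/macrophage-like, 5 in neutrophil-like, 1 in B-like and 3 in conventional dendritic-like cells, type I interferon genes of B-like cells (adjusted p = 0.999) and cytokine genes of conventional dendritic-like cells (0.532) reversed, and 1 gene was called in B-like and 613 in conventional dendritic-like cells.

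Within T sub-cluster 5, 57 genes and 1 list were called in CD8 T cells, and proliferation (0.137), interferon gamma (0.795), Gbp6 (-0.12) and Stmn1 (0.38) reversed. Within sub-cluster 7, 45 genes and 1 list were called, and proliferation (0.775), interferon gamma (0.0347), stress (0.775), Gbp6 (-0.50), Gbp9 (-0.032), Hspa1b (-0.38), Irf8 (0.032), Klrc1 (-0.85), Nr4a1 (-0.052) and Stmn1 (0.11) reversed. Within naive-like sub-clusters, 90 genes and 2 lists were called, and proliferation (0.0854), interferon gamma (0.0340), Cxcl10 (-1.22), Gbp6 (-0.29), Klrc1 (-0.14) and Stmn1 (0.58) reversed. The other sub-clusters gave 718 genes.

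Within NK-like cluster 6, 212 genes and 3 lists were called, with exhaustion (0.760), Klrg1 (0.074) and Cd200r1 (-0.18) reversed, and within cluster 11, 99 genes and 3 lists. In monocyte/macrophage-like cells cluster 1 gave 740 genes, with cytokines (0.850), macrophage RNA (0.942) and Ace (-0.025) reversed, and cluster 3 gave 350 genes and 4 lists, with stress (0.733) and macrophage RNA (0.743) reversed. Cluster 9 gave 467 genes and 7 lists, with MHC class I (0.485), Ace (-0.32), Fn1 (0.36), Ifit1bl1 (-0.22) and Mx2 (-0.080) reversed, and cluster 14 gave 456 genes, with Bnip3 at 0.088. Neutrophil-like cluster 10 gave 4 lists. B-like cluster 0 gave 23 genes, cluster 7 gave 5 genes and 3 lists, with cytotoxic genes (0.902) reversed, and cluster 13 gave 0 lists. Conventional dendritic-like cluster 27 gave 447 genes, with cytokines (0.298) reversed.

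TMM factors over classes gave 4 called classes, with CD8 T cells at 0.54 (adjusted p = 0.22), and 4 T sub-clusters after clustering without called genes. That clustering itself gave 0 where the planned one gave 3. Knockout minus control, the share of CD8 T cells with Havcr2 was -5.06 points without thinning and -0.63 in cells with a beta chain, Tox -8.17 and -6.88, and Tcf7 9.72 without thinning. The CD4 share in clones of 5 or more cells differed by -10.2 points.

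With a mouse left out, the lone mouse of a group is assumed to vary like the other group. Called genes then ranged from 42 to 1458 in CD8 T, 1 to 62 in CD4 conventional T, 227 to 1421 in NK-like, 59 to 2672 in monocyte/macrophage-like, 225 to 1198 in neutrophil-like, 56 to 1175 in B-like and 232 to 1514 in conventional dendritic-like cells, and from 1208 to 1726 between clone classes, 220 to 621 for genotype by clone class and 153 to 1225 between CD8 T and monocyte/macrophage-like cells. Called classes ranged from 0 to 10, T sub-clusters from 0 to 8 and, clustered without called genes, from 0 to 7, and called lists from 6 to 15 in CD4 conventional T and 7 to 11 in NK-like cells. The log2 change of the B-like share ranged from 2.90 to 3.20, of CD8 T from 1.08 to 1.41 and of monocyte/macrophage-like cells from -2.71 to -2.44. In CD8 T cells Ctla4 ranged from -0.047 to 0.24, Entpd1 from -0.53 to 0.15, Gzmb from -0.084 to 0.38, Prf1 from -0.054 to 0.095, Slamf6 from -0.52 to 0.69, Tcf7 from -0.15 to 1.21 and Tigit from -0.68 to 0.19. Tet2 ranged from -0.79 to 0.21 in CD4 conventional T and from -0.45 to 0.22 in neutrophil-like cells, and S100a8 from -0.66 to 1.06. The adjusted p of CD8 T lists ranged from 0.0450 to 0.533 for exhaustion, 9.17e-05 to 0.461 for stem-like and memory and 0.000394 to 0.811 for MHC class II.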

Other observations

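The values here were chosen after the data were seen. Receptor sequences were compared between mice as V segment and CDR3 amino acids of the beta chain. The knockout mice shared 20 such sequences, the control mice 8, and each pair of a knockout and a control mouse 9, with 1165, 1398, 964 and 838 sequences in knockout mice 1 and 2 and control mice 1 and 2. By V segment, J segment and CDR3 nucleotides the knockout pair shared 7, the control pair 3, and the mixed pairs 4 and 6 (knockout mouse 1 with control mice 1 and 2) and 2 and 4 (knockout mouse 2). The counts do not allow for set sizes, and no difference was tested.

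Among NK-like cells with an alpha chain, invariant NKT receptors made up 27.6% (20.9 to 35.1) and 24.0% (18.6 to 30.1) in the knockout and 16.3% (6.81 to 30.7) and 23.1% (8.97 to 43.6) in the control mice. The largest CD8 clones of knockout mice 1 and 2 had 59 and 33 cells, of which 52.5% and 63.6% lay in sub-cluster 0, against 188 cells and sub-cluster 9 in control mouse 2. Plasma-like cells, the antibody-secreting end stage of B cells, did not follow the B-like share, with 51 and 49 cells in the knockout and 66 and 41 in the control mice, and plasmacytoid dendritic-like cells numbered 197 and 184 against 3 and 49.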
